A study of Homo sapiens with 3 samples.

How the data were processed

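The samples were 3 DNA libraries from human H1 cells, an established embryonic stem cell line: input DNA from embryonic stem cells, chromatin immunoprecipitated with an E2A antibody from embryonic stem cells, and chromatin immunoprecipitated with the same antibody from neural progenitor cells derived from that line. E2A is the product of TCF3, a class I basic helix-loop-helix transcription factor that binds E-box sequences as a homodimer or with tissue-specific partners. Each group had 1 library and no replicate. The cells were untreated, and chromatin was sheared by sonication, per the labels' protocols.

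The authors deposited 1 file of peak calls with 5 tracks: summits and intervals for a list headed ESC, summits and intervals for a list headed ESC-SB, and merged regions. The submitters' processing notes name CASAVA 1.4, BWA, MACS2 and SICER and the build GRCh38, without saying which step used which tool. The track lines name hg38 and the letters se75. The threshold of the peak calls and any use of the input library are not given in the sources used here. The deposited score of each summit, called its height below, is a whole number, and neither its unit nor its scaling between the lists is stated in the file headers. Heights were therefore used only to rank or describe peaks within a list. Of the summits, 98.2% of the ESC list and 98.1% of the ESC-SB list lay on multiples of 16 bp, which limits their resolution.

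The header ESC matches the title of the E2A library from embryonic stem cells. The header ESC-SB matches the title of no sample, and the file has no track headed for neural progenitor cells. The ESC-SB list (1 list without a matched sample) is described under its header name, and no comparison between embryonic stem cells and neural progenitor cells is made. Whether the cells behind the ESC-SB list were untreated is therefore not established either. The read totals of the libraries and the input signal were not analysed here, so the depth is unknown.

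Positions are on hg38 and are given counting from 1. Genes came from the RefSeq table of the assembly GRCh38.p14, which shares its main chromosomes with hg38: 20037 protein-coding genes on chromosomes 1 to 22, X and Y. The table gives the start and end of each gene but no strand, exons or transcripts. The analysis fixed beforehand relied on 5′ ends; distances were measured here to the nearer of the 2 ends of a gene, so a peak close to a gene end is not necessarily at a promoter. The planned counts of E-boxes and other motifs, GC-matched controls and repeat content need the genome sequence, which was not used here, and were not run.

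Overlap between lists was counted from 1 bp. Chance overlap and chance location were estimated from 1000 random placements of the same peaks on the same chromosome, between its first and last annotated gene and outside stretches of over 3 Mb without an annotated gene. Peaks per chromosome were set against 10 times as many draws in proportion to the open length, and the share of draws as extreme in either direction was adjusted (Benjamini-Hochberg) over 23 chromosomes, leaving out Y. Random placement does not account for mappability or copy number. A total of 20 gene lists was fixed before the data were examined, holding pathways, cell states, other cell types and control groups; 1 list gene is not protein-coding and was left out. A gene counted as having a peak when a peak midpoint lay within 50 kb of either gene end. The number of such genes was compared with 10000 random gene lists matched in 4 bins of gene length and 4 bins of gene number within 100 kb, and a list was called when fewer than 2.5% of random lists had as many; 0.5 of the 20 lists would be called by chance. The share of random lists with as many genes was also adjusted over the 20 lists alone (Benjamini-Hochberg). Without replicates these values describe where the peaks of that list lie and are not tests between conditions. Shares carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Differences in median height carry percentile intervals from 1000 bootstrap draws over peaks, which are not replicates.

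Named peaks were the 25 highest of each list with the nearest protein-coding gene. From each gene list up to 6 members with a peak were eligible, nearest first, together with TCF3, TCF4, TCF12, ID1 to ID4, POU5F1, SOX2, NANOG, PAX6, SOX1, NODAL, LEFTY1 and LEFTY2 whether or not a peak was near. Clusters of peaks and dense windows were chosen after the values were seen. Alternatives covered the window around gene ends, all annotated genes, the highest 50% of each list by height, the matching of random lists, the minimum overlap, the span open to placement, neighbouring list genes counted as 1 locus, and the removal of chromosome 20 from 31 to 34 Mb. The procedure was tested on 20 simulated ESC-SB lists of 1888 peaks over the 20037 genes. It called 1 of the 20 random lists for gene ends and all 20 with 200 planted gene-end peaks. It called 1.5% of 400 gene lists without a planted effect, and the pluripotency list in all 20 simulations with 10 planted genes. The 200 planted gene-end peaks exceed the 76 ESC-SB peaks found within 1 kb of a gene end. The other simulated peaks were spread at random without clusters. The simulations therefore do not show how the procedure performs at the observed gene-end share, on clustered peaks or on the shorter ESC list. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1.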

Results

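Genome-wide E2A binding was mapped by chromatin immunoprecipitation and sequencing in H1 embryonic stem cells and in neural progenitor cells made from them, with an input library from the stem cells. The deposited calls comprised 283 peaks in the list headed ESC and 1888 peaks in the list headed ESC-SB, a header that matches neither E2A sample title and was given to no sample. Peaks had a median width of 297 bp in the ESC list (range 199 to 1101 bp) and 299 bp in the ESC-SB list (range 196 to 1430 bp). They covered 95.7 kb and 643 kb in total. Median summit heights, the authors' score, were 29 in the ESC list (range 14 to 97) and 28 in the ESC-SB list (range 13 to 146). The labels give 1 E2A library per cell type, the library behind the ESC-SB list is not established, and the number of reads is unknown, so no difference between the lists has a replicate check.

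The first comparison asked how far the 2 lists shared E2A sites. Of the 283 ESC peaks, 258 overlapped an ESC-SB peak (91.2%, exact 95% interval 87.2 to 94.2%), whereas 257 of the 1888 ESC-SB peaks overlapped an ESC peak (13.6%, 12.1 to 15.2%). Random placement gave a mean of 0.125 overlapping ESC peaks and a maximum of 3. The deposited 1912 merged regions were identical to those rebuilt from both lists, and held 256 regions with both, 25 with ESC peaks alone and 1631 with ESC-SB peaks alone. Within the ESC-SB list, the peaks shared with the ESC list had a median height of 53 (quartiles 36 and 69), against 27 (22 and 34) for the others. With the ESC-SB list divided by height into 4 parts of 472 peaks, 40.0% of the highest part overlapped an ESC peak (35.6 to 44.6%), against 7.42%, 5.30% and 1.70% of the lower parts. In the ESC list the shared peaks had a median height of 29 and the 25 others 26, and the lowest of 4 parts overlapped at 85.7% (75.3 to 92.9%).

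**Figure D1:**
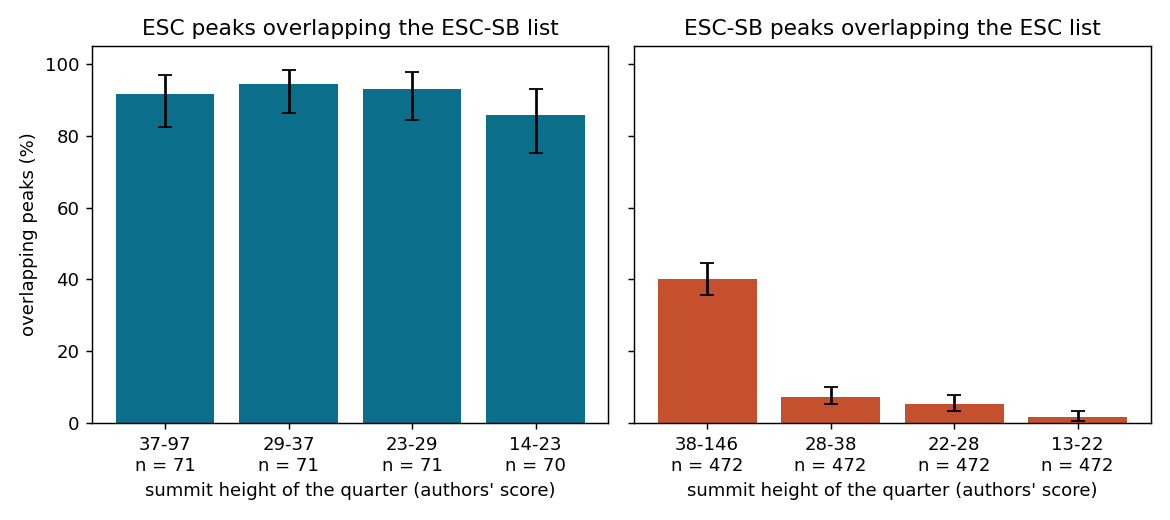
Share of peaks (%, vertical axis) that overlap the other list by at least 1 bp, for the ESC list and the ESC-SB list, in 4 parts of each list by summit height (horizontal axis, the authors' score, with the number of peaks); error bars are exact binomial 95% intervals. Overlap stays at 85.7% or more in each part of the ESC list and falls from 40.0% to 1.70% in the ESC-SB list.

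The tallest peak of both lists lay inside CBFA2T2, a transcriptional co-repressor of the MTG family, on chromosome 20 (ESC interval 33568335 to 33568783, height 97; ESC-SB interval 33568148 to 33568971, height 146). The next ESC peaks lay inside PPM1H, a protein phosphatase (height 79), and RPS6KC1 (77), then 910 kb from C4orf33 (76) and inside PDE4C, a cyclic AMP phosphodiesterase, 0.029 kb from a gene end (72). In the ESC-SB list CBFA2T2 was followed by a peak inside BCL2L1, which encodes the survival protein BCL-XL (133), then C4orf33 (124), PPM1H (118), PHLDA1 (118, at 65.7 kb), GPR176 (114) and FZD7, a Wnt receptor (112, at 37.6 kb). Further genes nearest to the 25 highest ESC-SB peaks included ASXL1, a Polycomb-associated chromatin regulator (106, inside and 0.993 kb from its end), CLYBL (104), TNFSF11 (101) and OTX2, a forebrain and neural progenitor transcription factor (94, at 36.7 kb). Of the 25 highest peaks, 24 in the ESC list and 23 in the ESC-SB list overlapped the other list, and 10 nearest genes were common to both sets. The exceptions were a peak in KDM2A, a histone demethylase (ESC height 57), and ESC-SB peaks near CD48 (108) and ACBD3 (91). The peaks inside CBFA2T2, BCL2L1 and ASXL1 all lay on chromosome 20 from 31 to 34 Mb, a region whose copy number was not analysed here.

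Peaks of the ESC-SB list lay near genes of pluripotency more often than near matched genes. Of 24 pluripotency genes 9 (37.5%) had a peak within 50 kb of a gene end, against a mean of 1.99 in random lists (share of random lists as high 0.0002, adjusted over the list alone 0.002). For comparison, 9.26% of the 20037 protein-coding genes had such a peak. The closest were at CRIPTO, a Nodal co-receptor (0.115 kb from a gene end, height 46), NANOG, a core pluripotency factor (1.001 kb, inside the gene, height 22), PRDM14 (9.68 kb, inside, height 23), the DNA methyltransferase gene DNMT3B (10.5 kb, height 29) and DPPA4 (16.6 kb, height 40). SOX2 had a peak at 42.5 kb (height 27). Strand was not used, so the nearer end may be either end of a gene, and the DNMT3B peak lay nearer to COMMD7 (8.44 kb). DPPA4 and a neighbouring gene of the list had the same nearest peak. With neighbours counted as 1 locus, 8 of 22 loci had a peak at any of their genes (mean of random lists, drawn with 1 gene per locus, 1.85). None of the nearest peaks of these 9 genes overlapped an ESC peak, but CRIPTO had a second ESC-SB peak that did, and 1 of the 24 pluripotency genes, CRIPTO, had a peak in the ESC list (28.7 kb, height 40).

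FGF and Wnt signalling genes also passed the threshold against matched lists in the ESC-SB list, but neither passed the adjustment. FGF genes with a peak numbered 7 of 26 (mean of random lists 2.38, adjusted over the list alone 0.0520): SPRY4, a feedback inhibitor of FGF signalling, at 0.373 kb, FGF17 at 1.57 kb, FGF2, a growth factor of stem cell medium, at 1.75 kb, FGF1 at 4.07 kb, FGFR2 at 18.1 kb, FGFR1 at 27.9 kb and 1 further gene. The FGF17 peak lay inside the neighbouring gene DMTN. The Wnt list had 8 of 38 (mean 3.47, adjusted 0.105), among them TCF7L1, a repressor of the Wnt response, at 1.99 kb, TCF7L2 at 5.05 kb, LEF1 at 8.05 kb, FZD7 at 10.3 kb and AXIN2, a negative feedback target of Wnt, at 11.3 kb. The Wnt call was lost with a window of 10 kb (3 genes, mean 0.892, share as high 0.0621) and with the gene body plus 10 kb (3 genes, mean 1.92, share 0.303), and the FGF call was kept in both. Neural progenitor genes with a peak numbered 6 of 31 (mean 2.62, adjusted 0.176), not past the threshold at 50 kb. All 6 had their peak within 10 kb: ZIC5 at 2.69 kb, SOX21 at 2.76 kb, OTX2 at 3.44 kb, the intermediate filament gene NES at 3.53 kb, ZIC2 at 7.19 kb and MEIS2 at 8.95 kb. ZIC5 and ZIC2 shared 1 peak. With the window set at 10 kb the neural progenitor list was called (mean of random lists 0.691, adjusted over the list alone 0.004). At that window 5 other lists were called too, the FGF list with an adjusted share of 0.021 and the pluripotency, E protein and Id, mesendoderm and muscle lists with adjusted shares from 0.0567 to 0.0657. Counted over the gene body plus 10 kb, the neural progenitor list was called again (6 genes, mean 1.41, adjusted over the list alone 0.014). The pluripotency list had 4 genes in that setting (mean 0.823, adjusted 0.0425). Under the other alternatives the neural progenitor list was not called.

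Of the remaining lists, the histone genes alone were called in the ESC-SB list at 50 kb. Nodal, TGF-beta and BMP genes had 5 of 35 (mean 3.35), with CRIPTO and NODAL (5.43 kb, inside, height 36) closest, followed by BMP7, SMAD3 and INHBB. Epithelial-mesenchymal genes had 5 of 29 (mean 2.69), including CLDN6 at 0.110 kb, the epithelial adhesion gene EPCAM at 0.144 kb and CDH1 at 41.7 kb. Mesendoderm genes had 3 of 23, with CER1, a secreted Nodal antagonist, at 0.088 kb. Proneural genes had 3 of 24, Notch genes 4 of 28, neural crest genes 2 of 18, cell cycle genes 5 of 29, chromatin regulators 6 of 35 and housekeeping genes 5 of 30. Among lists for other cell types, lymphocyte genes had 4 of 28, muscle genes 3 of 22, fibroblast genes 0 of 15 and liver genes 0 of 16, and olfactory receptors had 0 of 22. Matched random lists averaged 1.35 genes for the fibroblast list, 1.33 for the liver list and 1.68 for the olfactory receptors. These counts of 0 therefore lay within the random range and do not show that peaks avoided these genes. Histone genes had 9 of 21 in both lists (adjusted 0.002), but a single peak inside H1-2 on chromosome 6 accounted for all 9; counted by locus, 1 of 6 had a peak and the call was lost in both lists.

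In the ESC list the Nodal, TGF-beta and BMP genes had 3 of 35 (mean of random lists 0.539), past the threshold but with an adjusted share of 0.17 over the list alone. These were CRIPTO at 28.7 kb, BMP7 (inside, 34.4 kb from a gene end) and SMAD3, a transducer of Nodal and activin signals, at 35.6 kb. The call was lost with a window of 10 kb, where 0 genes had a peak, and with the gene body plus 10 kb, where 1 had a peak (mean of random lists 0.358, share as high 0.306). In the highest 50% of ESC peaks by height the same count of 3 genes stood against a mean of 0.275 and passed the adjustment (0.028), and over the 6 alternatives the adjusted share ranged from 0.028 to 1. Besides the histone genes no other list was called. Single members with a peak included ID3 at 1.79 kb, FGF1 at 4.08 kb, CLDN6 at 6.12 kb, FOXA3 at 8.38 kb, AXIN2 at 11.3 kb and FOXO1 at 14.2 kb, and each of these peaks overlapped an ESC-SB peak. With 283 peaks, 1.52% of protein-coding genes had a peak within 50 kb, and the random mean was under 1 gene for each of the 20 lists, so a list with fewer genes than expected was not detectable.

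**Figure D2:**
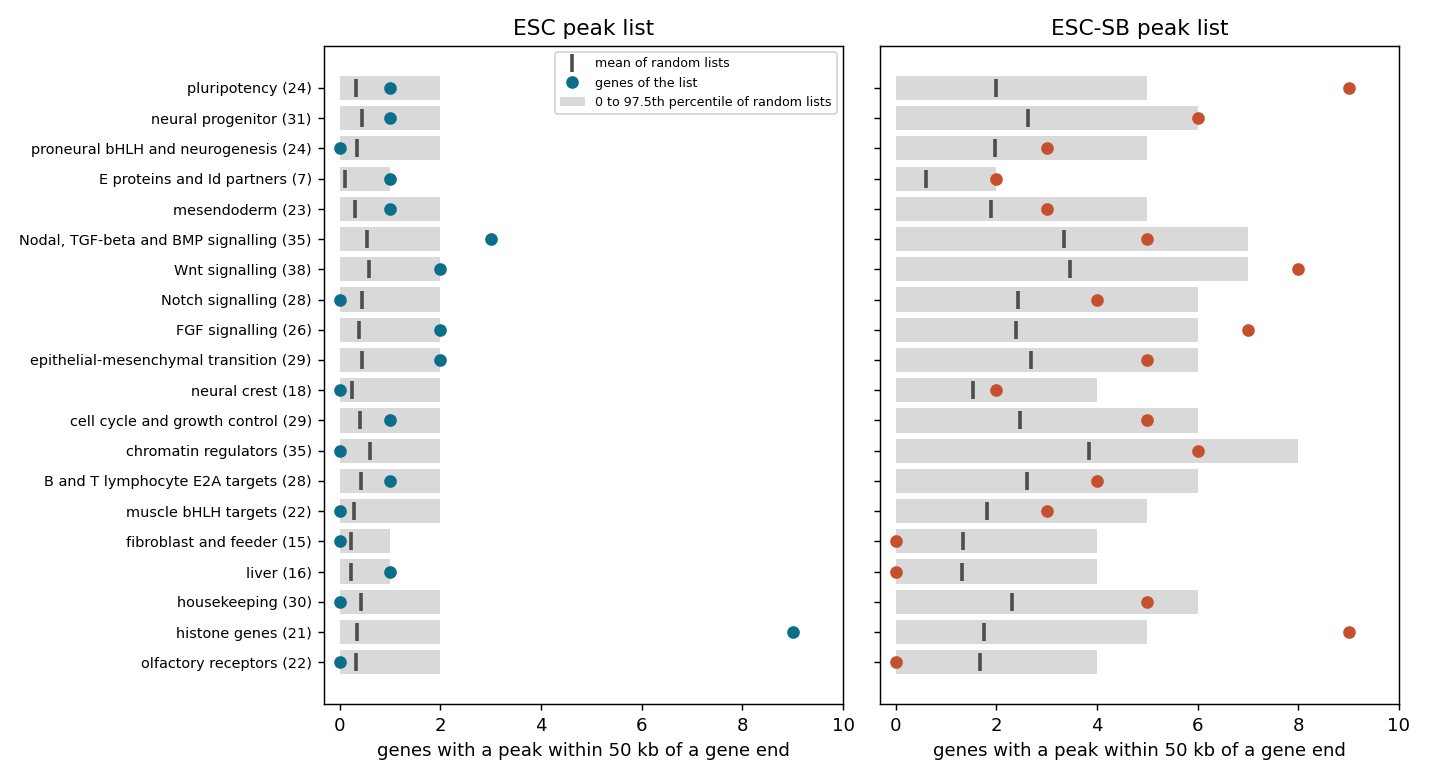
Number of genes with a peak within 50 kb of a gene end (horizontal axis) for each gene list (vertical axis, number of genes in parentheses), in the ESC and ESC-SB peak lists; dots are the lists, ticks the mean and grey bars the range from 0 to the value that at most 2.5% of 10000 matched random lists exceed. Pluripotency stands at 9 genes against a mean of 1.99 in the ESC-SB list, and the 9 histone genes rest on 1 peak.

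Genes of the E protein network were examined individually. TCF3 itself had no peak nearby, the closest being 683 kb away in the ESC list and 1325 kb away in the ESC-SB list. The related E protein genes TCF4 and TCF12 held 3 and 1 ESC-SB peaks inside their bodies, 53.5 kb or more and 92.4 kb from a gene end, and none from the ESC list. The genes of the Id proteins, which dimerize with E proteins and block DNA binding, differed: ID3 had peaks in both lists at 1.79 and 1.83 kb (heights 31 in ESC and 55 in ESC-SB, which are not on a stated common scale). ID1 had 4 ESC-SB peaks within 50 kb, the nearest at 1.01 kb, and its nearest ESC peak was 102 kb away. ID2 and ID4 had none nearer than 464 kb and 525 kb. By gene ends, 2 of 7 genes of the E protein and Id list had an ESC-SB peak (mean of random lists 0.603, not called). With the gene body plus 10 kb, 4 of 7 did (mean 0.408, adjusted over the list alone 0.006). TCF4 and TCF12 were added by the peaks inside their long bodies. Matching used only 4 bins of gene length, so this adjusted share may reflect gene length. Without chromosome 20 from 31 to 34 Mb, which holds ID1, 1 of 7 had a peak by gene ends (mean 0.600). The closest ESC-SB peaks to POU5F1, SOX1, LEFTY2, LEFTY1 and PAX6 were 227, 90.2, 171, 223 and 1073 kb away, outside the window.

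Most peaks of both lists lay far from gene ends. The median distance to the nearest protein-coding gene end was 43.7 kb in the ESC list and 41.8 kb in the ESC-SB list. Peaks within 1 kb of a gene end made up 5.30% of the ESC list (15 of 283, exact 95% interval 3.00 to 8.59%) and 4.03% of the ESC-SB list (76 of 1888, 3.18 to 5.01%). Random placement gave 2.71% and 2.56%, so the shares were 1.96 and 1.58 times the random mean and past the threshold against placements. For the highest 50% of the ESC-SB list by height the share was 2.97% and within the random range. Gene bodies held 44.9% of ESC peaks and 46.3% of ESC-SB peaks, against 44.7% and 44.3% at random, neither beyond the random range. ESC-SB peaks within 1 kb of a gene end had a median height of 25 against 28 elsewhere (difference -3, bootstrap 95% interval over peaks -5.5 to -1), a difference that was 0 with a window of 5 kb (interval -2 to 2). In the ESC list the medians were 40 and 28 (difference 12, interval -2 to 20).

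Along the chromosomes, ESC-SB peaks were sparse on X, with 49 peaks or 0.495 times the number expected from its open length (adjusted share of random draws as extreme 0.0046), and dense on chromosome 13, with 88 peaks or 1.39 times (adjusted share 0.0391). With placement over the whole span the call on chromosome 13 was lost (1.24 times, adjusted share 0.252). It was also lost in the highest 50% of peaks by height (1.42 times, adjusted share 0.164). The call on X held in both settings, at 0.505 and 0.282 times (adjusted share 0.0046 in each). The draws do not account for copy number, so a lower copy number of X and sparser binding cannot be told apart. The ESC list had 7 peaks on X, 0.471 times the expected number, and 0 of 23 chromosomes passed the adjustment, with 1 at an unadjusted share under 0.05. The densest 3 Mb window of the ESC-SB list was on chromosome 20 from 31 to 34 Mb, with 15 peaks, whereas the densest window of random placements held 8.38 on average and 12 at most. It included peaks near ID1 (4 within 50 kb), inside BCL2L1, at ASXL1, 10.5 kb from DNMT3B and at CBFA2T2. Its median ESC-SB height was 36 against 28 over the list, and 3 ESC peaks of the same window had a median height of 66.

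**Figure D3:**
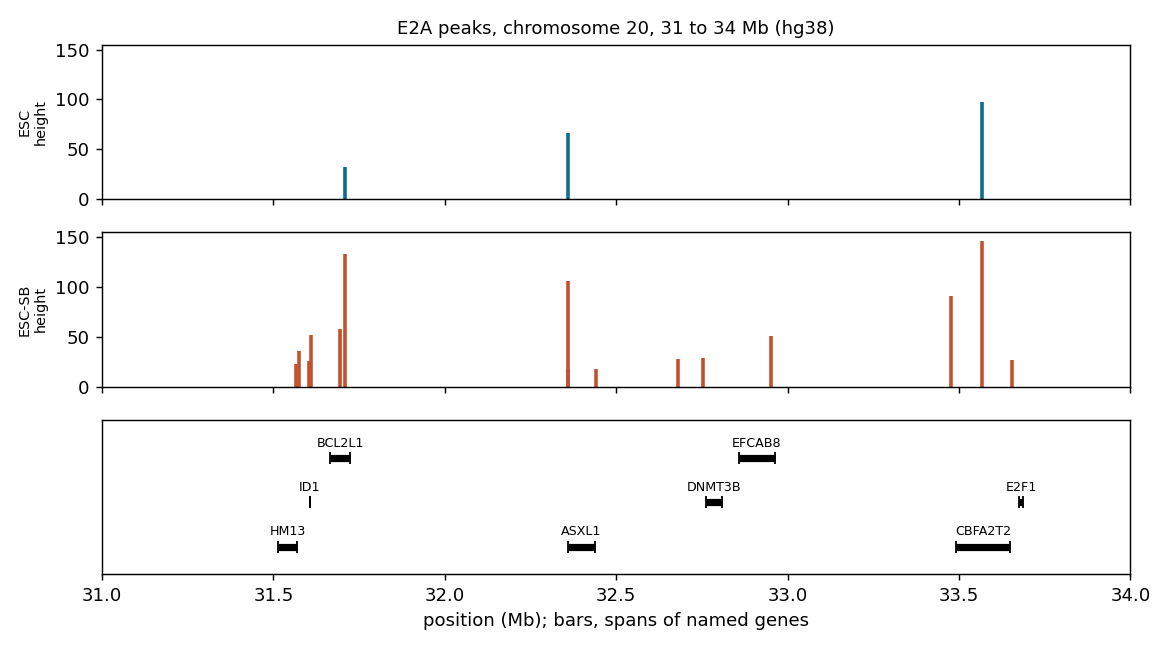
E2A peaks on chromosome 20 from 31 to 34 Mb (hg38; horizontal axis, Mb) as vertical lines with the summit height (the authors' score) for the ESC list and the ESC-SB list, above the spans of named genes; heights of the lists are not on a stated common scale. The window holds 3 ESC peaks and 15 ESC-SB peaks, the tallest inside CBFA2T2 in both lists.

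Peaks also gathered in clusters with at most 50 kb between neighbours. The largest ESC-SB cluster held 8 peaks over 93.3 kb inside CLYBL on chromosome 13 (99625304 to 99718598), 3 of which overlapped ESC peaks; a further peak lay between the neural transcription factor genes ZIC5 and ZIC2. Clusters of 5 ESC-SB peaks lay near FGFR1, LRIG1, a feedback inhibitor of growth factor receptors, and the crystallin genes CRYBB1 and CRYBA4. Clusters of 4 lay at BMP7, EPCAM, ATP11A, and HM13 with ID1, and outside but nearest to PODXL. The largest ESC cluster held 5 peaks over 36.7 kb inside KDM2A on chromosome 11 (67217687 to 67254425), with heights from 22 to 57. None overlapped an ESC-SB peak, and the ESC-SB list had 0 peaks in KDM2A.

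**Figure D4:**
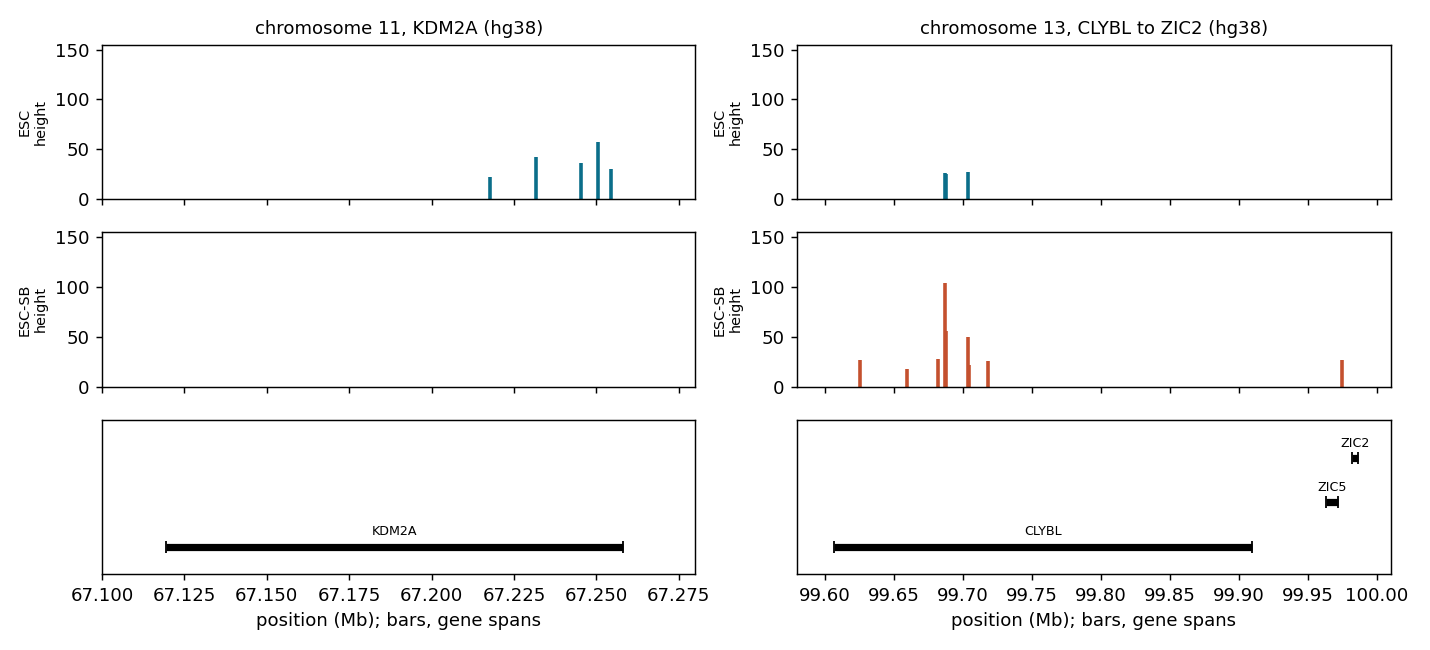
E2A peaks as vertical lines with the summit height (the authors' score) in the ESC list and the ESC-SB list, over KDM2A on chromosome 11 and from CLYBL to ZIC2 on chromosome 13 (hg38; horizontal axes, Mb), above gene spans. KDM2A holds 5 ESC peaks and 0 ESC-SB peaks, and CLYBL holds 3 ESC peaks and 8 ESC-SB peaks.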

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

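The choices on the window of chromosome 20, the open span, loci, chromosome counts under other settings and the 5 kb window for heights were made after the data were seen. The overlap of the lists held under each alternative run: 90.8% and 90.1% of ESC peaks, and 13.6% and 13.5% of ESC-SB peaks, with an overlap of at least 50% of the shorter peak and with the highest 50% of each list by height. By construction the highest 50% hold 141 ESC and 944 ESC-SB peaks. The number of ESC peaks limits the ESC-SB share in each setting, so its stability adds no check beyond that of the ESC share. In the highest 50% the ESC-SB share at gene ends was 2.97% and no longer beyond random placement, and the ESC share within genes was 44.7%, below the random mean of 45.1% where the whole list lay just above it; neither was past the threshold, and the cause was not tested. The ESC-SB share within genes passed the threshold with all annotated genes (60.8% against 58.6% at random) and with placement over the whole span (46.3% against 42.1%). The number of called gene lists in the ESC list, 2 in the main setting, was 1 within 10 kb, where both main calls were lost and the E protein and Id list was called from 1 gene (share as high 0.0239, adjusted 0.444), 0 for the gene body plus 10 kb and 1 by locus; in the ESC-SB list, 4 in the main setting, it stayed between 3 and 6. Pluripotency and FGF signalling were called in the ESC-SB list under all 6 alternatives, pluripotency with adjusted shares from 0.002 to 0.094. By locus, a locus counted when any of its genes had a peak, whereas random lists drew 1 gene per locus. The random mean is therefore low for loci of several genes, and the calls by locus carry less weight. Wnt signalling lost its call within 10 kb and for the gene body plus 10 kb. The number of chromosomes past the threshold in the ESC-SB list fell from 2 to 1 with placement over the whole span, which lost chromosome 13; the highest 50% lost it too and added chromosome 10 (adjusted share 0.0368). The lower height of ESC-SB peaks near gene ends, a difference of -3 within 1 kb, was 0 within 5 kb and no longer excluded 0; the cause was not tested. Of 44 alternatives over 14 results, the other 33 kept their direction and side of the threshold, or, for counts, stayed within 1.5 times, and for overlaps, within the exact interval. The alternatives for the share of peaks with an E-box, E-box density, the repeat share and peaks under 50% repeats were not run, because they need the genome sequence. No paired analysis was possible because each group has 1 library. The unknown depth limits what the absence of a peak shows in either list.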

Other observations

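The tests on copies of chromosome 20 were chosen after the values were seen; the other tests below were written down before their results.

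Genes outside the fixed lists were also nearest to several ESC-SB peaks. Examples of clusters of 3 peaks, with at most 50 kb between neighbours, lay inside LAMB1, a laminin chain (heights 22 to 33), and inside GREB1L (30 to 35). Others lay inside SNRPN, an imprinted gene (22 to 60), and inside UTRN, which encodes the cytoskeletal protein utrophin (29 to 45). A further cluster lay outside but nearest to IL6, a cytokine gene (21 to 40). Of the clusters named here, the SNRPN cluster had 1 peak that overlapped an ESC peak and the others had none. Peaks near pluripotency genes were not the tall ones: the 10 ESC-SB peaks within 50 kb of their ends had a median height of 27.5 against 28 for the list, at the 45.0th percentile of random sets, which argues against the hypothesis that these are the strongest sites.

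The ESC list was far shorter than the ESC-SB list. One hypothesis is that fewer sites passed the threshold in the ESC library because its signal was weaker, and the highest 10% of the ESC-SB list, of which 62.4% overlapped an ESC peak (exact 95% interval 55.1 to 69.4%), is consistent with it, as is the decline of overlap with height. The same values would arise if binding itself were lower in the ESC library, and a biological difference stays open and untested, because read totals were not analysed here, neither list has a replicate, and the labels do not tie the ESC-SB header to a sample.

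The 5 ESC peaks inside KDM2A had no ESC-SB counterpart. Random spread is argued against, since 0 of 1000 placements (0%) put 5 ESC peaks within 50 kb. A failure to call these sites in the ESC-SB library may seem improbable, because 94.9% of the other ESC peaks at least as tall as their median of 36 overlapped an ESC-SB peak (75 of 79, interval 87.5 to 98.6%), but the interval reaches below the bound of 90% set beforehand, so this stays open. Extra copies or stray DNA of this region in one library were not tested, as the input signal was not analysed here, and no biological explanation was tested.

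ESC-SB peaks were densest on chromosome 20 from 31 to 34 Mb, next to BCL2L1, ID1 and DNMT3B, a region in which cultured human pluripotent cells often gain copies. Random spread is argued against: 0 of 1000 placements (0%) gave a window of 15 peaks. The 231 other windows with at least its 52 protein-coding genes held a median of 2 peaks and at most 9, so gene density alone did not usually bring as many. That 0% of them held 15 was fixed when the densest window was chosen, so this result cannot exclude gene density. A gain of copies would tend to raise heights in the window, whose median of 36 lay at percentile 96.96 of random sets of ESC-SB peaks, short of the threshold that leaves 2.5% above it, and 5 of the 15 peaks were lower than the list median of 28 and 1 equalled it. The 3 ESC peaks in the window had a median height of 66, against 29 over the ESC list. A gain of copies and true clustering of E2A sites cannot be told apart, because the input signal and copy number were not analysed here.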
